A study of Mus musculus with 20 samples.

How the data were processed

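Polyadenylated RNA was measured by stranded sequencing in 20 libraries of mouse embryonic stem cells converted to epiblast stem cells. Per the labels, cells of a female line (PGK) and a male line (E14) were kept in 2i and then grown with activin A and Fgf2 on fibronectin, split at day 4 and later at short intervals until day 30, and RNA was extracted with Trizol and treated with DNase. Each line was sampled at 5 stages in 2 experiments, diff2 and diff3, which gave 10 groups of 2 libraries. The 2 late stages pool days per the labels: days 19 to 23 and days 27 to 30.

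Per the submitters' processing notes, reads were processed with CASAVA 1.8.2 against GRCm38 (mm10), and Cuffdiff and DESeq2 are named without stating which values each made. The aligner, the gene annotation and the use of strand in counting are not given in the sources used here. Raw counts per gene, a signal that is the counts divided by 1 size factor per library, and log2 values after a variance-stabilizing transformation were deposited, per the file headers. Checked against the counts, the deposited signal differed from counts over a constant by at most 9.8e-10 within any library. Each table has 23361 entries, of which 27 bear names turned into dates and 4 a repeated name. A chromosome was assigned to 23199 genes, 21699 by a symbol of GENCODE release M21, 211 by a RefSeq symbol and 1289 by a synonym, and 162 had none. The list of mitochondrially encoded genes is not analysed here.

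CPM values are raw counts scaled to a common library total, given as mean ± SD with n = 2. Depth ranged from 2020254 to 26936415 counts. In the 2 shallow libraries, E14 diff3 at day 0 and day 4, the floor of 3 counts equals 0.888 and 1.48 CPM, against 0.111 to 0.253 CPM in the others. Gapdh measured 0.93 to 12.44 CPM, which is low for this gene, and no use is made of it. Genes without counts in a group are given as at least N-fold, with 3 counts over that group's libraries as the floor, and genes with 1 to 3 counts there are given as levels only. The bound uses the mean CPM of the other group, which 1 library can dominate. Medians of lists with genes without counts in a group are also given with the bound in their place. No 2 libraries were duplicates, with Pearson r between replicates of 0.842 to 0.984 across genes.

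Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM size factors, filterByExpr with a minimum count of 10, and robust quasi-likelihood tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons within a line used a fit of its 10 libraries with 5 residual degrees of freedom. Those between lines, and the differences of a change between lines, used a fit of all 20 libraries with 10. In all 17 comparisons were made. The common biological coefficient of variation was 0.435 in PGK, 0.516 in E14 and 0.485 over both. Tested on simulated data, the PGK day 4 comparison recovered 51 of 100 genes changed 4-fold and 10 of 96 changed 2-fold, and the E14 comparison 21 of 96 and 1 of 100. The difference between lines recovered 6 of 100 and 0 of 99, so genes not called may still have changed. Each simulation changed few genes and held all others flat. In the real PGK day 4 comparison 2260 genes were called, which makes the adjustment less strict, so these shares may not carry over to it. X-linked genes were compared with autosomal genes by the difference of median log2 fold changes and by camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation. A simulated X-linked shift of 1.41-fold was returned as 0.52 on the log2 scale, and none as −0.05.

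A set of 33 gene lists was fixed beforehand: naive, primed and core pluripotency, primitive streak, definitive endoderm, neuroectoderm, extraembryonic endoderm, trophoblast, fibroblast and feeder, germ line genes silenced by DNA methylation, two-cell stage, DNA methylation machinery, polycomb regulators, X inactivation centre, escape genes, Y-linked genes, microRNA biogenesis, published targets of miR-290 and miR-302, of let-7 and of miR-200, imprinted genes and microRNA hosts, responses to FGF and ERK, Nodal and activin, and Wnt, glycolysis, respiratory chain, p53, cell cycle, serine and amino acid stress, histones, immediate early and heat shock, retrotransposon and interferon response, and mitochondrially encoded genes. All list tests were adjusted together. Some lists share members, such as Dusp6 and Krt18, which the primed list also holds, so their results are not independent. Genes were named by a rule written beforehand: 17 are always reported, up to 3 with the smallest adjusted p per list described, and up to 6 largest rises and falls per comparison that reach 1 log2 CPM in the higher group and move alike in both experiments, without predicted genes and pseudogenes. Some genes that the rule names are not reported here.

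Per the labels, libraries with the same number come from the same differentiation experiment, which pairs them. Among days 0, 4 and 10, where the diff2 libraries carry a library code, experiment differences correlated between stages at 0.439 to 0.575 in PGK and 0.139 to 0.25 in E14. For pairs of stages with a later one the correlation was −0.154 to 0.148 in PGK and −0.261 to 0.16 in E14. A difference shared through an experiment can thus not be told from one of the library code. A fit with experiment as a block was run as an alternative. Other alternatives were RLE size factors, no low-count filter, a term for the library code carried by 6 diff2 libraries, a joint fit of both lines, DESeq2 1.42.0, limma on the deposited log2 values, each library left out, and X-linked genes of at least 5 log2 CPM. Leaving out the 6 coded libraries or both shallow libraries was added after the data were seen. Where 1 library remains in a group it is assumed to vary like the other groups.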

Results

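Stranded mRNA sequencing followed mouse embryonic stem cells during their conversion to epiblast stem cells, the primed pluripotent state that resembles the post-implantation epiblast. A female line called PGK and a male line called E14 were grown in 2i medium, which keeps cells in the naive state, and then moved to medium with activin A and Fgf2. Libraries were made at day 0, day 4, day 10, once between days 19 and 23 and once between days 27 and 30, in 2 differentiation experiments named diff2 and diff3. This gave 20 libraries in 10 groups, and every mean ± SD in the text has n = 2. Total counts per library ranged from 2020254 to 26936415. The diff3 libraries of E14 were the shallow ones at day 0, with 3376500 counts, and at day 4, with 2020254 counts. The diff2 libraries at days 0, 4 and 10 of both lines, 6 in all, carry a library code in their titles that the others lack. Each sex is represented by a single line, so sex and line cannot be told apart in any comparison between them.

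The first comparison followed PGK cells over the 4 days after they left 2i. Genes of the naive state dropped sharply: Klf4, a reprogramming factor (GRCm38, chromosome 4, 55527143 to 55532466), fell from 353 ± 99.6 to 5.87 ± 0.228 CPM, Tfcp2l1 from 1604 ± 44.8 to 43.6 ± 16.9 CPM and Tbx3 from 263 ± 98.3 to 4.6 ± 1.33 CPM. Genes of the post-implantation epiblast appeared in their place. Fgf5, a growth factor of the epiblast (chromosome 5, 98254184 to 98277030), rose from 0.209 ± 0.163 to 168 ± 49.7 CPM, and Dnmt3b, a de novo DNA methyltransferase, from 43.5 ± 3 to 1145 ± 461 CPM. The Wnt receptor gene Fzd2 rose from 2.07 ± 0.285 to 41.8 ± 1.45 CPM. Pou5f1, which both states use, stood at 1188 ± 161 CPM at day 0 and 1143 ± 180 CPM at day 4 and did not pass the test (log2 fold change −0.12, SE 0.31, adjusted p = 0.843). Nanog fell by 2.92 on the log2 scale (SE 0.31, adjusted p = 0.00026), Sox2 by 2.42 (SE 0.49, adjusted p = 0.00844), Esrrb by 4.21 (SE 0.53, adjusted p = 0.000621) and Zfp42 by 3.24 (SE 0.55, adjusted p = 0.00352). Otx2 at 108 ± 3.59 against 48.9 ± 20.1 CPM and Dnmt3l at 80.7 ± 97 against 6.88 ± 3.25 CPM did not pass. Of 15284 genes tested with edgeR, 2260 changed, 1276 higher and 984 lower, while limma on the deposited values called 1385 higher and 1624 lower. DESeq2 called 3515, a term for the library code raised the count to 3698, and leaving out the diff3 library at day 4 lowered it to 1366.

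By list, 20 of the 24 measured naive pluripotency genes fell and 0 rose (21 fell when adjusted over the list alone), with a median log2 fold change of −3.43. Against the other genes, camera gave adjusted p = 1.5e-11 for this list, and adjusted p = 0.232 with an estimated correlation. Of 27 primed pluripotency genes 21 rose and 0 fell (23 rose when adjusted over the list alone), with a median of 3.62. For the primed list camera gave adjusted p = 4.03e-14, and adjusted p = 0.0164 with an estimated correlation. Among 19 targets of FGF and ERK signalling 8 rose and 0 fell (10 rose when adjusted over the list alone), including Dusp6, the ERK phosphatase, from 2.97 ± 1.09 to 185 ± 87.4 CPM, and the immediate early gene Egr1 from 0.326 ± 0.00182 to 47.1 ± 5.64 CPM. Camera gave adjusted p = 2.08e-05 here, and adjusted p = 0.259 with an estimated correlation. Nodal and activin targets rose in 6 of 17 cases (7 rose and 1 fell when adjusted over the list alone), among them Lefty1, a Nodal inhibitor, from 5.04 ± 3.45 to 123 ± 78.4 CPM, and Skil from 77.1 ± 17.7 to 286 ± 12.6 CPM. That list had adjusted p = 0.00715, and adjusted p = 0.227 with an estimated correlation. Of 19 genes of the miR-200 and epithelial to mesenchymal transition list 8 rose and 2 fell (9 rose and 2 fell when adjusted over the list alone). The risers included epithelial genes, with the splicing regulator Esrp1 going from 1.09 ± 0.0473 to 165 ± 26.1 CPM. The adhesion molecule gene Epcam rose from 26.3 ± 2.96 to 226 ± 26.2 CPM and the keratin Krt18 from 3.55 ± 1.06 to 69.4 ± 16.3 CPM. For the miR-200 list camera gave adjusted p = 0.00278, and adjusted p = 0.258 with an estimated correlation.

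Published let-7 targets rose in 8 of 21 cases and fell in 2 (9 rose and 2 fell when adjusted over the list alone). For the let-7 list camera gave adjusted p = 0.00433, and adjusted p = 0.601 with an estimated correlation. Lin28a, whose protein blocks let-7 maturation (chromosome 4, 134003330 to 134018841), rose from 6.37 ± 2.13 to 478 ± 58.1 CPM and Lin28b from 11.8 ± 5.73 to 128 ± 36.7 CPM. Myc rose from 1.92 ± 1.11 to 74.3 ± 46.4 CPM, while Plagl1, an imprinted zinc finger gene, fell from 217 ± 33.1 to 20.3 ± 4.17 CPM. In the list of imprinted genes and microRNA hosts 8 of 22 rose and 2 fell (12 rose and 2 fell when adjusted over the list alone). Among the risers Peg3, a paternally expressed zinc finger gene, went from 54.2 ± 2.05 to 486 ± 243 CPM. For the list of imprinted genes and microRNA hosts camera gave adjusted p = 0.00375, and adjusted p = 0.227 with an estimated correlation. Lists of lineage genes moved in part without passing as lists. Of 21 primitive streak genes 6 rose (adjusted p = 0.0709), of 14 definitive endoderm genes 6 rose (adjusted p = 0.0528), of 15 Wnt targets 5 rose (adjusted p = 0.0551), and in each the count was unchanged upward when adjusted over the list alone. The streak gene T, which encodes Brachyury, went from 0.805 ± 0.449 to 251 ± 315 CPM, with 28.2 CPM in diff2 and 474 CPM in diff3 at day 4. The largest rises by the naming rule were Epha1, from 0.111 ± 0.0418 to 184 ± 100 CPM, and genes with no counts at day 0: Lrrc3 was at least 178-fold higher, Cnr1 at least 170-fold, Tmem54 at least 140-fold, Tmem59l at least 122-fold and Jakmip2 at least 107-fold. Among the falls, Bhmt was at least 312-fold lower, Aqp8 at least 311-fold, Mgat4c at least 291-fold, Sp100 at least 270-fold and Sgcz at least 164-fold, all without counts at day 4. DESeq2 called none of these 5 falls. The bounds use the mean of the 2 day 0 libraries, and for Mgat4c and Sgcz they rest largely on diff3. Without the diff3 library at day 0 their fitted log2 fold changes were −7.76 and −8.37. With both day 0 libraries kept and the diff3 library at day 4 left out they were −11.89 and −11.06. T was not called without the diff2 library (adjusted p = 0.0831) or the diff3 library (adjusted p = 0.0625) at day 0.

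**Figure D1:**
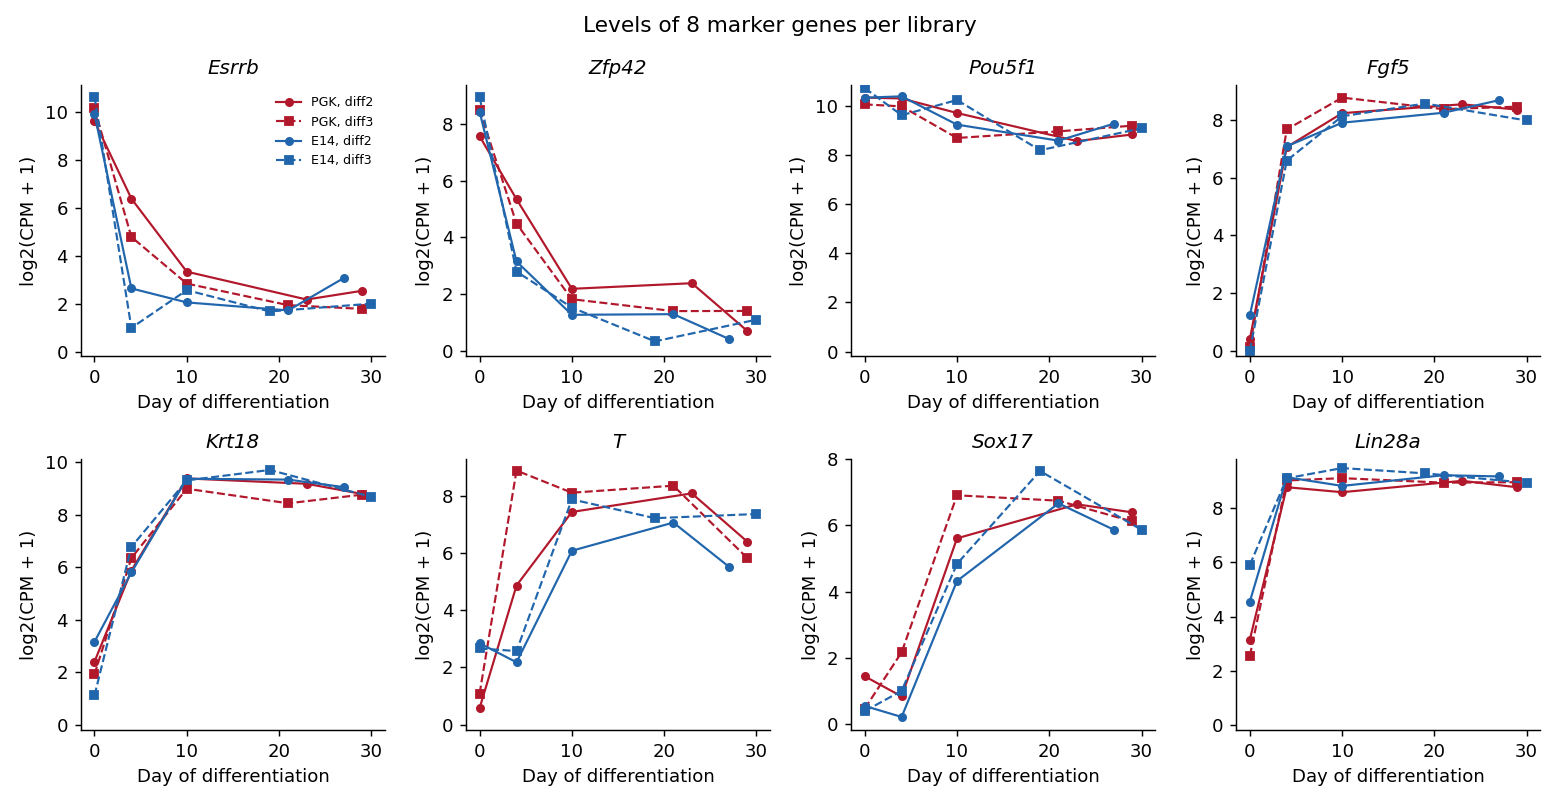
Expression of 8 marker genes as log2(CPM + 1) against day of differentiation, 1 point per library, with PGK in red and E14 in blue, diff2 as circles on solid lines and diff3 as squares on dashed lines. Esrrb and Zfp42 drop by day 4 in both lines, Fgf5 and Lin28a rise, Sox17 is higher from day 10, and T differs between PGK and E14 at day 4, at 251 ± 315 against 4.24 ± 1 CPM (SD, n = 2).

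Between day 4 and day 10 some germ line genes fell and some endoderm genes rose in PGK. Ddx4, a germ cell RNA helicase, fell from 50.3 ± 11.9 to 0.786 ± 0.202 CPM, and Mov10l1, Hormad1, Mael and Syce1, which act in meiosis or in piRNA production, had no counts at day 10 and were at least 161-fold, 210-fold, 194-fold and 180-fold lower. Sox17, an endoderm transcription factor (chromosome 1, 4490931 to 4497354), rose from 2.12 ± 1.91 to 83.7 ± 50.7 CPM, Foxa1 from 1.7 ± 0.821 to 33.8 ± 14.7 CPM and the transcription factor gene Foxq1 from 2.56 ± 1.74 to 96.2 ± 64 CPM. Krt18 rose from 69.4 ± 16.3 to 589 ± 113 CPM and Acta2, smooth muscle actin, from 5.73 ± 1.46 to 119 ± 46.5 CPM. The naive genes Tdh, a threonine dehydrogenase (chromosome 14, 63492347 to 63509092), and Zfp42 fell, from 83.1 ± 44.2 to 1.95 ± 1.3 CPM and from 30.5 ± 13 to 3.04 ± 0.718 CPM. Of 23 germ line genes silenced by DNA methylation 11 fell and 0 rose (18 fell when adjusted over the list alone), with a median log2 fold change of −4.59, or −4.5 with genes at 0 set to their bound. Camera gave adjusted p = 4.72e-22, and adjusted p = 0.16 with an estimated correlation. Definitive endoderm genes rose in 6 of 14 cases (13 when adjusted over the list alone, median 3.23). For the endoderm list camera gave adjusted p = 1.05e-13, and adjusted p = 0.159 with an estimated correlation. Extraembryonic endoderm genes, which share Sox17 and Gata6 with that list, rose in 4 of 18 cases (9 when adjusted over the list alone). For the extraembryonic endoderm list camera gave adjusted p = 1.41e-07, and adjusted p = 0.238 with an estimated correlation. The list of fibroblast and feeder genes rose in 3 of 20 cases (10 when adjusted over the list alone). For the fibroblast list camera gave adjusted p = 2.13e-06, and adjusted p = 0.31 with an estimated correlation. Two-cell stage genes had been higher as a list at day 4 than at day 0 (median 3.19, 0 of 10 singly). For the two-cell list camera gave adjusted p = 0.000987, and adjusted p = 0.412 with an estimated correlation. At day 10 against day 4 they did not pass singly, 0 of 10, but 7 were lower when adjusted over the list alone, and the list was lower than other genes (median −6.85, or −3.8 with genes at 0 set to their bound). For the two-cell list camera gave adjusted p = 4.27e-11, and adjusted p = 0.185 with an estimated correlation. In total 231 of 15284 genes changed, 160 higher and 71 lower, with Spink3 at 57.2 ± 9.2 against 0.0701 ± 0.0992 CPM and Usp18, an interferon-induced gene, at 11.8 ± 3.18 against 0.0351 ± 0.0496 CPM among the largest rises. Of the 14 called genes named for this step 6 lost their call without the diff2 library at day 4 and 6 without the diff3 library at day 10, among them Sox17 (adjusted p = 0.0513 and 0.0548), Ddx4 (adjusted p = 0.0513 and 0.0887) and Zfp42 (adjusted p = 0.0743 and 0.2). The count varied widely with the setting: 53 without the diff2 library at day 4, 153 without the diff2 library at day 10, and 52 without the diff3 library at day 10. It was 351 with experiment as a block, 655 with a term for the library code, 639 without the coded libraries, 133 in the joint fit and 439 without a low-count filter. Limma on the deposited values gave 362 and DESeq2 855.

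After day 10 no single gene passed in PGK from a stage to the next. Fgf5 measured 369 ± 96.9 CPM at day 10, 352 ± 29.2 CPM at days 19 to 23 and 340 ± 17.4 CPM at days 27 to 30, and Dnmt3b 850 ± 183, 735 ± 11.4 and 856 ± 23.5 CPM at the same stages. From day 10 to days 19 to 23 edgeR called 0 genes, with 208 at an unadjusted p under 0.05, and DESeq2 called 5. From days 19 to 23 to days 27 to 30 edgeR again called 0, with 231 at an unadjusted p under 0.05, DESeq2 called 4 and the fit without the coded libraries 2. Fibroblast and feeder genes lay higher at days 19 to 23 than at day 10 (median 1.14, 2 of 20 higher when adjusted over the list alone). For the fibroblast list camera gave adjusted p = 2.31e-06, and adjusted p = 0.31 with an estimated correlation. Interferon response genes lay lower at days 27 to 30 than at days 19 to 23 (median −1.01, adjusted p = 5.18e-06, and adjusted p = 0.258 with an estimated correlation). So did primitive streak genes (median −0.77, adjusted p = 0.000154, and adjusted p = 0.426 with an estimated correlation), where T measured 69.9 ± 19.6 against 300 ± 39.6 CPM. Without the diff3 library of days 19 to 23 the streak list no longer passed (median −0.4, adjusted p = 0.0992).

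Compared with day 0, most naive genes were lower in PGK cells of days 27 to 30. Tdh measured 0.0655 ± 0.0259 against 608 ± 243 CPM, Esrrb (chromosome 12, 86361117 to 86521628) fell from 963 ± 250 to 3.64 ± 1.67 CPM, and Prdm14, a repressor of FGF signalling, had no counts at the end and was at least 1708-fold lower. Pou5f1 fell by 1.26 on the log2 scale (SE 0.31, adjusted p = 0.0153), a call lost without the diff2 library at day 0 (adjusted p = 0.0582) or either library of days 27 to 30 (adjusted p = 0.102 for diff2 and 0.0534 for diff3). Fgf5 reached 340 ± 17.4 CPM against 0.209 ± 0.163 CPM, and Lefty1 rose from 5.04 ± 3.45 to 693 ± 54.8 CPM. Lin28a rose from 6.37 ± 2.13 to 467 ± 43.3 CPM and the imprinted noncoding RNA gene H19 (chromosome 7, 142575529 to 142578143) from 2.14 ± 1.53 to 318 ± 60 CPM. Of 24 naive genes 22 fell and 1 rose, with a median log2 fold change of −7.04. For the naive list camera gave adjusted p = 1.35e-13, and adjusted p = 0.227 with an estimated correlation. Primed genes rose in 22 of 27 cases (median 3.86, adjusted p = 2.18e-10, and adjusted p = 0.0318 with an estimated correlation). Both counts were the same when adjusted over the list alone. Definitive endoderm genes rose in 11 of 14 cases (12 when adjusted over the list alone), with the thyrotropin-releasing hormone gene Trh from 7.92 ± 2.02 to 417 ± 200 CPM and Foxa1 from 0.36 ± 0.179 to 37.9 ± 0.2 CPM. For the endoderm list camera gave adjusted p = 5.28e-07, and adjusted p = 0.232 with an estimated correlation. Germ line genes fell in 18 of 23 cases and rose in 1 (19 fell and 1 rose when adjusted over the list alone, median −8.77, or −6.52 with genes at 0 set to their bound). For the germ line list camera gave adjusted p = 3.2e-10, and adjusted p = 0.258 with an estimated correlation. The riser was Tdrkh, a piRNA pathway gene, from 1.09 ± 0.875 to 48.7 ± 4.2 CPM. Fibroblast and feeder genes rose in 14 of 20 cases and fell in 1, equally when adjusted over the list alone (median 5.65, or 3.45 with genes at 0 set to their bound), with Tagln, a smooth muscle cytoskeletal gene, from 1.09 ± 0.0473 to 143 ± 18.6 CPM. For the fibroblast list camera gave adjusted p = 1.83e-06, and adjusted p = 0.307 with an estimated correlation. Imprinted genes rose in 10 of 22 cases and fell in 2 (16 and 2 when adjusted over the list alone). For the imprinted list camera gave adjusted p = 0.000225, and adjusted p = 0.159 with an estimated correlation. Of 15284 genes 3833 changed, 1994 higher and 1839 lower. The balance turned with RLE size factors (1925 higher and 1950 lower), DESeq2 (2492 and 2622) and limma on the deposited values (2172 and 2510). Among the genes without counts at 1 end, Ooep was at least 3504-fold lower, Tcl1 at least 2661-fold, Rpl10l at least 2353-fold, Calcoco2 at least 1940-fold and Sohlh2 at least 1515-fold. Acta2 was at least 799-fold higher, Spink3 at least 514-fold, the collagen gene Col3a1 at least 356-fold, Aff2 at least 269-fold and Wisp1 at least 232-fold. Without the diff3 library of days 27 to 30 the count was 2208.

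In E14 cells the naive state was left over the same 4 days. Tfcp2l1 fell from 1820 ± 57.6 to 10.3 ± 2.87 CPM, Esrrb from 1285 ± 450 to 3.11 ± 3 CPM and Klf4 from 504 ± 65.9 to 2.65 ± 1.15 CPM. Dnmt3b (chromosome 2, 153649450 to 153687730) rose from 26.7 ± 1.35 to 1657 ± 798 CPM, Fgf5 from 0.671 ± 0.949 to 115 ± 27.9 CPM, Lin28a from 40.7 ± 25.8 to 557 ± 9.97 CPM and Dusp6 from 5.97 ± 3.28 to 200 ± 11 CPM. Fn1, fibronectin, fell from 4767 ± 335 to 279 ± 19 CPM while Esrp1 rose from 0.819 ± 0.74 to 220 ± 43.1 CPM and Epcam from 36.7 ± 6.6 to 423 ± 39.6 CPM. Pou5f1 (log2 fold change −0.45, SE 0.41, adjusted p = 0.535), Sox17, T and Xist did not pass. All 21 naive genes that passed, of 23, fell (22 when adjusted over the list alone), with a median of −6.61. For the naive list camera gave adjusted p = 1.71e-22, and adjusted p = 0.00632 with an estimated correlation. Primed genes rose in 18 of 27 cases and fell in 0 (20 rose when adjusted over the list alone, median 3.98, or 3.45 with genes at 0 set to their bound). For the primed list camera gave adjusted p = 1.03e-08, and adjusted p = 0.227 with an estimated correlation. FGF and ERK targets rose in 9 of 19 cases (10 when adjusted over the list alone). For the FGF and ERK list camera gave adjusted p = 0.000188, and adjusted p = 0.227 with an estimated correlation. Trophoblast genes fell in 3 of 14 cases (4 when adjusted over the list alone, median −2.36), namely Tfap2c from 123 ± 56.6 to 0.258 ± 0.364 CPM, Tead4 from 119 ± 39.6 to 2.01 ± 0.657 CPM and Gata2 from 25.1 ± 19 to 0.184 ± 0.26 CPM. For the trophoblast list camera gave adjusted p = 0.0124, and adjusted p = 0.232 with an estimated correlation. Without the diff2 library at day 0 the trophoblast median was 0 (adjusted p = 0.057) and without the coded libraries −0.12 (adjusted p = 0.0645), where the FGF and ERK list had adjusted p = 0.0859. Of 14501 genes 1386 changed, 748 higher and 638 lower (752 and 761 without the diff3 library at day 0), and the median over all genes shifted by 0.15 on the log2 scale, by 0.76 without the diff2 library at day 0 and by −0.09 without the diff2 library at day 4. Among the largest rises were Cnn1, at least 220-fold higher, Tmem154, at least 149-fold, Cpt1b, at least 143-fold, Mrc2, at least 140-fold, and Jakmip2, at least 118-fold, none with counts at day 0. Aspa was at least 117-fold lower, Gprc5a at least 104-fold and Aldh3a1 at least 56.7-fold, which was not called with experiment as a block (adjusted p = 0.0625). Without both shallow libraries 4 of the 21 called genes named for this step lost their call, among them Fn1 (adjusted p = 0.0645) and Gata2 (adjusted p = 0.134). The count was 887 without both shallow libraries, 688 without the diff2 and 474 without the diff3 library at day 4. It was 4517 without the diff2 library at day 0, 6812 without the coded libraries, 2423 in the joint fit and 2856 with DESeq2.

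From day 4 to day 10 few genes passed in E14. Sox17 rose from 0.569 ± 0.596 to 23.3 ± 6.1 CPM, the chemokine receptor gene Cxcr4 from 0.505 ± 0.0145 to 15.7 ± 3.31 CPM. T (chromosome 17, 8434423 to 8442496) rose from 4.24 ± 1 to 151 ± 119 CPM, and Bmp2, a growth factor without counts at day 4, was at least 83.5-fold higher. The intermediate filament genes Vim, from 91.5 ± 45.6 to 759 ± 66.6 CPM, and Krt8, from 35.7 ± 23.7 to 427 ± 7.73 CPM, rose. So did the retinoic acid hydroxylase gene Cyp26a1 from 1.52 ± 2.05 to 86.6 ± 3.6 CPM and the matrix gene Tnc from 0.395 ± 0.142 to 30.4 ± 15.9 CPM. Ddx4 fell from 52.1 ± 3.25 to 0.443 ± 0.038 CPM, Rpl10l was at least 84-fold lower, and the stress response genes Chac1, from 62.6 ± 35.3 to 2.22 ± 0.267 CPM, and Trib3, from 72.8 ± 19 to 5.96 ± 0.2 CPM, also fell. Definitive endoderm genes rose in 2 of 14 cases (11 when adjusted over the list alone, median 4.42). For the endoderm list camera gave adjusted p = 2.76e-11, and adjusted p = 0.227 with an estimated correlation. Germ line genes fell in 2 of 21 cases (15 when adjusted over the list alone, median −4.66). For the germ line list camera gave adjusted p = 1.47e-15, and adjusted p = 0.168 with an estimated correlation. The serine and amino acid stress list fell in 2 of 15 cases (3 when adjusted over the list alone, median −1.16). For the stress list camera gave adjusted p = 1.33e-09, and adjusted p = 0.232 with an estimated correlation. Interferon response genes lay higher with 0 of 14 passing singly (6 when adjusted over the list alone, median 2.4). For the interferon list camera gave adjusted p = 1.08e-09, and adjusted p = 0.228 with an estimated correlation. Of 14501 genes only 27 passed, 21 higher and 6 lower. All 12 called genes named for this step lost their call without the diff2 library at day 4, 10 without the diff3 library at day 4, 10 without the diff2 and 8 without the diff3 library at day 10. The count itself was 0 without the diff2 library at day 4, 6 without the diff3 library at day 4 and 9 without the diff2 library at day 10. It was 78 without both shallow libraries, 1111 without the coded libraries, 208 in the joint fit, 139 without a low-count filter and 520 with DESeq2.

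Later steps in E14 gave 0 calls with edgeR. From day 10 to days 19 to 23 the unadjusted p was under 0.05 for 938 genes and DESeq2 called 274. The count was 11 with experiment as a block, 3 with RLE size factors, 18 in the joint fit, 59 without a low-count filter, 10 without both shallow libraries and 1673 without the coded libraries. Sox17 measured 150 ± 70.1 against 23.3 ± 6.1 CPM (adjusted p = 0.227), Chac1 49.9 ± 6.91 against 2.22 ± 0.267 CPM (adjusted p = 0.0539) and the imprinted gene Grb10 3402 ± 601 against 812 ± 107 CPM (adjusted p = 0.0775). Definitive endoderm genes lay higher, 10 of 14 when adjusted over the list alone (median 2.62, adjusted p = 9.93e-10, and adjusted p = 0.232 with an estimated correlation). The p53 targets lay lower, 9 of 20 when adjusted over the list alone (median −1.13, adjusted p = 1.36e-09, and adjusted p = 0.258 with an estimated correlation). From days 19 to 23 to days 27 to 30 edgeR called 0 genes, with 0.731 percent of 14501 at an unadjusted p under 0.05, DESeq2 called 4 and the fit without the coded libraries 2. Interferon response genes lay lower at that step (median −1.15, adjusted p = 2.75e-09, and adjusted p = 0.232 with an estimated correlation).

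At days 27 to 30 E14 cells had lost naive and gained primed transcripts against day 0. Klf4 measured 2.18 ± 0.381 CPM and Tfcp2l1 13.5 ± 2.17 CPM, Fgf5 332 ± 113 CPM, Lefty1 577 ± 202 CPM against 8.02 ± 2.48 CPM at day 0, and the neural cadherin gene Cdh2 rose from 1.12 ± 0.742 to 145 ± 24.2 CPM. Grb10 rose from 294 ± 24.1 to 3229 ± 507 CPM and the growth factor gene Igf2 from 0.817 ± 0.101 to 389 ± 242 CPM. Pou5f1 at 585 ± 53.3 against 1502 ± 287 CPM did not pass (adjusted p = 0.0552). Naive genes fell in 20 of 23 cases (21 when adjusted over the list alone, median −7.51). For the naive list camera gave adjusted p = 1.52e-22, and adjusted p = 0.00632 with an estimated correlation. Primed genes rose in 21 of 27 cases and fell in 1 (22 and 2 when adjusted over the list alone, median 4.98, or 4.7 with genes at 0 set to their bound). For the primed list camera gave adjusted p = 9.34e-08, and adjusted p = 0.227 with an estimated correlation. Definitive endoderm genes rose in 11 of 14 cases, equally when adjusted over the list alone (median 6.31). For the endoderm list camera gave adjusted p = 1.44e-05, and adjusted p = 0.394 with an estimated correlation, or 0.0708 without the diff2 library at day 0 and 0.101 without the coded libraries. Fibroblast and feeder genes rose in 9 of 19 cases and fell in 1 (14 and 1 when adjusted over the list alone, median 5.63, or 4.32 with genes at 0 set to their bound). For the fibroblast list camera gave adjusted p = 6.5e-06, and adjusted p = 0.426 with an estimated correlation, or 0.0539 with a median of 9.52 without the coded libraries. Germ line genes fell in 12 of 21 cases and rose in 1 (15 and 1 when adjusted over the list alone, median −6.91, or −5.85 with genes at 0 set to their bound). For the germ line list camera gave adjusted p = 1.67e-06, and adjusted p = 0.292 with an estimated correlation. Of 14501 genes 1990 changed, 1266 higher and 724 lower, with a median over all genes of 0.19, which was 0.87 without the diff2 library at day 0 and 0.82 without the coded libraries. Accsl was at least 1714-fold lower, Ooep at least 1413-fold, Dmgdh at least 1372-fold, Rpl10l at least 1260-fold and Crxos1 at least 907-fold. Col1a2 was at least 530-fold higher, Dkk1 at least 340-fold, Klhl4 at least 328-fold, Mrc2 at least 260-fold, Spink3 at least 246-fold and Adamts1 at least 203-fold. The count was 670 without the diff2 library of days 27 to 30, and 645 without the diff3 library. It was 4941 without the diff2 library at day 0, 8039 without the coded libraries, 3086 in the joint fit and 3597 with DESeq2.

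**Figure D2:**
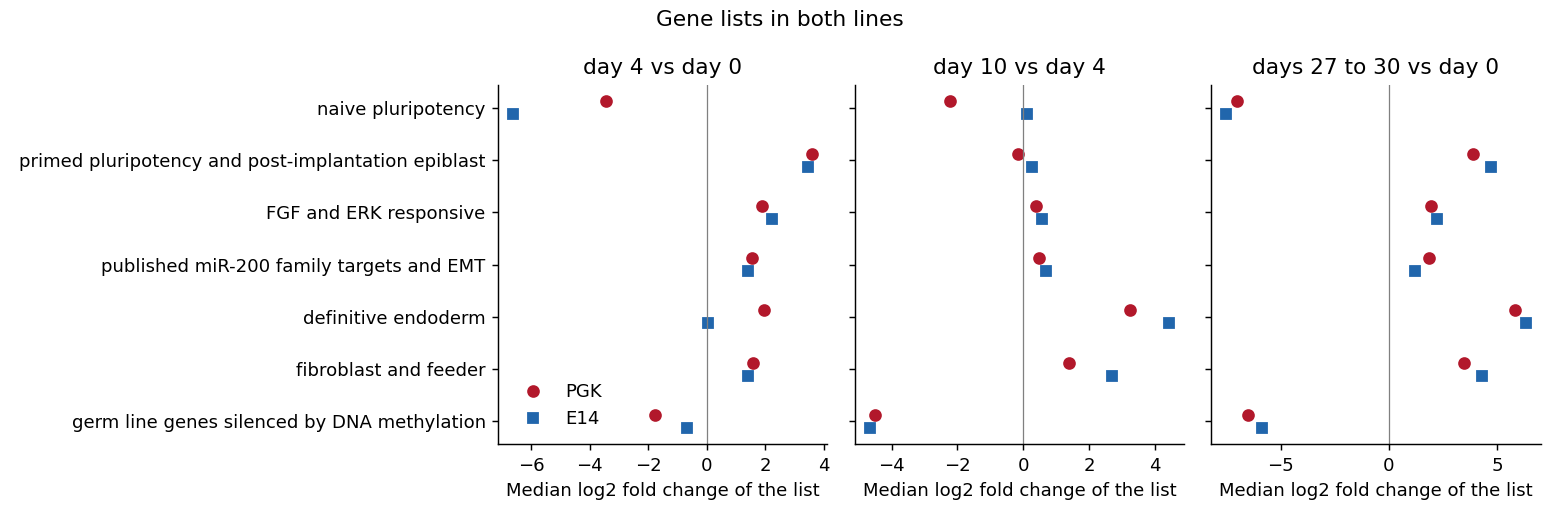
Median log2 fold change of 7 gene lists, with genes at 0 in a group set to their bound, for day 4 against day 0, day 10 against day 4 and days 27 to 30 against day 0, PGK in red and E14 in blue, 1 point per line and comparison. Naive genes lie at −3.43 in PGK and −6.61 in E14 at day 4 against day 0, and germ line genes at −4.5 and −4.66 at day 10 against day 4.

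The 2 lines were compared for overlap of their calls, which come from separate libraries. The library code lies at the same stages in both lines, so an effect of it could be shared. The counts by chance assume that every gene is equally likely to be called. Of 14317 genes tested in both, 528 were higher in both at day 4 against day 0 where 66.5 would be shared by chance, 390 were lower in both where 41.6 would be, and 4 moved in opposite directions. At days 27 to 30 against day 0 the shared counts were 1003 higher (174.7 by chance) and 583 lower (81.6 by chance), with 3 opposite. Across genes, which are not independent replicates, the log2 fold changes of PGK and E14 had Pearson r = 0.701 for day 4 against day 0, 0.521 for day 10 against day 4, 0.434 and 0.085 for the later steps, and 0.819 for days 27 to 30 against day 0.

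Xist, the noncoding RNA that coats the X chromosome to be silenced (X, 103460366 to 103483254), rose in PGK from 21.9 ± 13.3 CPM at day 0 to 1635 ± 441 CPM at day 4 (log2 fold change 6.15, SE 0.57, adjusted p = 0.000143). It measured 1511 ± 101 CPM at day 10, 1160 ± 253 CPM at days 19 to 23 and 675 ± 372 CPM at days 27 to 30. In E14, which has a single X, Xist stayed at or under 17.5 CPM in every library. Tsix, its antisense partner, measured 52.9 ± 69.8 CPM in PGK at day 4 with 102 CPM in the coded diff2 library and 3.61 CPM in diff3, and 120 against 1.07 CPM at day 10. Whether strand was used in counting is not given in the sources used here, so reads of Xist and Tsix may have been mixed in the coded libraries and Tsix is reported as uncertain. At day 0 X-linked genes were higher in PGK than in E14 by 1.17 on the log2 scale over the autosomal median, or 2.25-fold, with 26 of 619 passing upward and 0 downward (adjusted p = 1.29e-25, and adjusted p = 0.0161 with an estimated correlation). The excess was 0.36 at day 4 (adjusted p = 9.72e-05, and adjusted p = 0.311 with an estimated correlation), 0.03 at day 10 (adjusted p = 0.755), −0.01 at days 19 to 23 (adjusted p = 0.982) and −0.03 at days 27 to 30 (adjusted p = 0.6). For X-linked genes of at least 5 log2 CPM the gap at day 0 was smaller. Relative to the mean of the libraries they lay at 0.617 and 0.514 in PGK, and at −0.317 and −0.314 in E14. Within PGK, X-linked genes moved down relative to autosomal genes by day 4, at −0.52 (52 of 606 rose and 87 fell, adjusted p = 0.000233, and adjusted p = 0.0791 with an estimated correlation). By days 27 to 30 the value was −0.81 (72 rose and 205 fell, adjusted p = 4.96e-06, and adjusted p = 0.0544 with an estimated correlation). Usp9x, an X-linked deubiquitinase gene, fell from 1635 ± 578 to 730 ± 15.6 CPM by day 4, a call lost without the diff3 library at day 4 (adjusted p = 0.0507). In E14 the X-linked median lay above the autosomal one at day 4 against day 0, by 0.36 (adjusted p = 0.0116, and adjusted p = 0.6 with an estimated correlation). Per library, for genes of at least 5 log2 CPM, it went from −0.314 to 0.085 in diff3, where both libraries are shallow, and from −0.317 to −0.248 in diff2. At days 27 to 30 it lay above by 0.6 (85 of 514 rose and 17 fell, adjusted p = 0.00472, and adjusted p = 0.576 with an estimated correlation). Leaving out the diff2 library at day 0 or all coded libraries moved that last value to 1.23 and 1.26, and the PGK against E14 value at day 0 to 2.45 and 2.36. The X-linked change differed between the lines, by −0.83 at day 4 (adjusted p = 6.29e-12, and adjusted p = 0.0588 with an estimated correlation) and by −1.19 at days 27 to 30 (adjusted p = 1.56e-24, and adjusted p = 0.0161 with an estimated correlation). Both differences combine the fall in PGK with the rise in E14, which at day 4 lay mainly in the shallow diff3 libraries. They were not refitted with libraries left out.

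**Figure D3:**
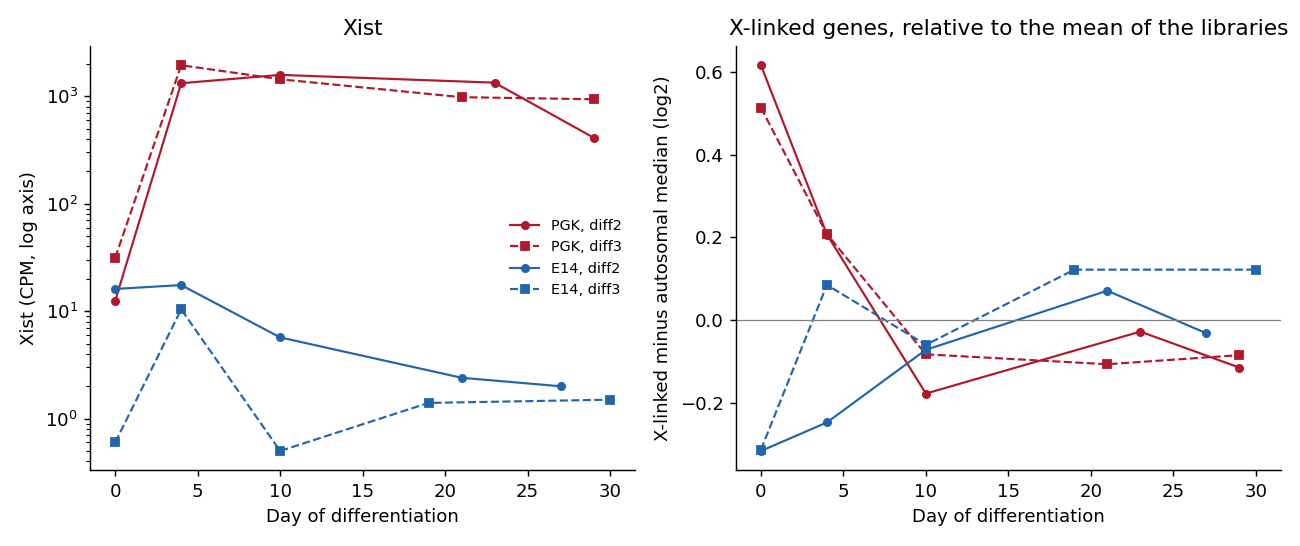
Left, Xist in CPM on a log axis against day of differentiation, 1 point per library, PGK in red and E14 in blue, diff2 as circles on solid lines and diff3 as squares on dashed lines. Right, the X-linked minus the autosomal median log2 CPM of each library, over 216 X-linked genes of at least 5 log2 CPM, relative to the mean of the libraries: PGK starts at 0.617 and 0.514 at day 0 and lies at −0.178 and −0.083 at day 10, and E14 starts at −0.317 and −0.314.

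Between the lines, genes on the sex chromosomes and autosomal genes differed at each stage. Of the Y-linked genes Ddx3y (Y, 1260771 to 1286629), Eif2s3y and Uty were lower in PGK at all 5 stages, the female line having at most 4 counts in a group, and 3 of 4 measured list members passed each time. At day 0 the Y-linked median was −11.49, or −10.43 with genes at 0 set to their bound, and 4 were lower when adjusted over the list alone. For the Y-linked list camera gave adjusted p = 3.48e-19, and adjusted p = 0.000304 with an estimated correlation. Hprt, an X-linked purine salvage gene (X, 52988137 to 53021659), measured 391 ± 9.04 CPM in PGK against 1.04 ± 1.06 CPM in E14 at day 0, and 192 ± 1.84 against 0.522 ± 0.126 CPM at days 27 to 30. Plagl1 (chromosome 10, 13060504 to 13131694) was higher in PGK at each stage, at 217 ± 33.1 against 7.58 ± 1.51 CPM at day 0, and had no E14 counts at days 27 to 30, where it was at least 570-fold higher. H19 measured 219 ± 88 against 1.87 ± 1.71 CPM at day 10 and 318 ± 60 against 0.642 ± 0.0441 CPM at days 27 to 30. At that last stage the X-linked glycolysis gene Pgk1 (X, 106187100 to 106203699) measured 13 ± 10.9 CPM in PGK and 168 ± 43.5 CPM in E14. At day 0 Lin28a was lower in PGK, at 6.37 ± 2.13 against 40.7 ± 25.8 CPM, while Lats2, a kinase gene of the Hippo pathway, was higher at 16.3 ± 6.27 against 0.633 ± 0.476 CPM. The copper monooxygenase homologue Moxd1 (chromosome 10, 24223517 to 24302790) had no E14 counts at day 0 and was at least 366-fold higher in PGK, and Xlr5b was at least 153-fold higher. Imprinted genes as a list lay higher in PGK at days 27 to 30 (2 of 23 higher, 5 higher and 5 lower when adjusted over the list alone, median 0.68). For the imprinted list camera gave adjusted p = 0.00375, and adjusted p = 0.124 with an estimated correlation, or 0.0875 with a median of 0.39 without the diff2 library of PGK. Lin28a, Lats2 and Xlr5b lost their calls without the diff3 library of PGK at day 0 (adjusted p = 0.0746, 0.0517 and 0.133) or of E14 (adjusted p = 0.0636, 0.0806 and 0.135), and Xlr5b also without the diff2 library of PGK (adjusted p = 0.101). H19 lost its call at day 10 without the diff3 library of E14 (adjusted p = 0.12) or the coded libraries (adjusted p = 0.0964), and at days 27 to 30 without the diff2 or the diff3 library of E14 (adjusted p = 0.11 and 0.145). Pgk1 lost its call without the diff2 library of PGK (adjusted p = 0.157) or of E14 (0.0682) or the diff3 library of E14 (0.235).

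At day 4 PGK held more naive transcripts than E14. Esrrb measured 54.6 ± 39.6 against 3.11 ± 3 CPM and was the 1 naive gene of 24 that passed, with 13 higher when adjusted over the list alone. The naive list had a median difference of 2.16, adjusted p = 1.05e-13, and adjusted p = 0.0408 with an estimated correlation. Trophoblast genes were higher in 1 of 17 cases (2 when adjusted over the list alone, median 2.42, or 2.06 with genes at 0 set to their bound), with Tfap2c at 16.4 ± 0.805 against 0.258 ± 0.364 CPM. For the trophoblast list camera gave adjusted p = 8.89e-08, and adjusted p = 0.00632 with an estimated correlation. Wnt targets were higher in 1 of 15 cases, T at 251 ± 315 against 4.24 ± 1 CPM (5 when adjusted over the list alone, median 2.6, or 1.25 with genes at 0 set to their bound). For the Wnt list camera gave adjusted p = 8.04e-06, and adjusted p = 0.227 with an estimated correlation. Glycolysis genes lay lower in PGK, 0 of 18 singly and 2 when adjusted over the list alone (median −0.78). For the glycolysis list camera gave adjusted p = 4.45e-07, and adjusted p = 0.227 with an estimated correlation. Grb10 was lower at 127 ± 30.1 against 740 ± 113 CPM. Esrrb, Tfap2c, T and Grb10 each lost their call without the diff2 library of E14 (adjusted p = 0.0707, 0.149, 0.186 and 0.063), without its diff3 library (adjusted p = 0.218, 0.244, 0.387 and 0.191) and without both shallow libraries. Without the diff3 library of PGK the T difference was 2.8 against 5.99 on the log2 scale (adjusted p = 0.251).

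Numbers of genes that differed between the lines with edgeR, of 15732, fell with time. At day 0 there were 80 (45 higher in PGK, 35 lower, 1931 at an unadjusted p under 0.05, and a median over all genes of 0.15, or 0.8 without the diff2 library of E14) and at day 4 26 (22 and 4). There were 10 at day 10 (7 and 3), 10 at days 19 to 23 (6 and 4) and 9 at days 27 to 30 (5 and 4). DESeq2 called 700, 235, 78, 89 (28 higher and 61 lower) and 24. The day 0 count was 41 and 43 without each PGK library in turn, 24 without the diff3 and 3317 without the diff2 library of E14. Other settings gave 35 without both shallow libraries, 185 with a term for the library code, 181 without a low-count filter and 4633 without the coded libraries. At day 4 it was 8 without the diff2 and 6 without the diff3 library of E14 and 15 without both shallow libraries. It was 44 with experiment as a block, 66 with the code term, 71 without a low-count filter and 538 without the coded libraries. At day 10 it was 16 with the block, 20 with the code term and 504 without the coded libraries. At days 19 to 23 it was 5 without the diff2 and 6 without the diff3 library of E14 and 446 without the coded libraries. At days 27 to 30 it was 5 without either E14 library, 14 with the code term and 43 without the coded libraries.

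The change over time was tested for a difference between the lines. For day 4 against day 0, 12 of 15732 genes differed, 6 each way. Moxd1 fell in PGK from 65.4 ± 23 to 6.78 ± 2.35 CPM and rose in E14 from 0 to 13.2 ± 0.897 CPM (adjusted p = 0.000644 for the difference). Sema5a, an axon guidance gene, fell in PGK from 63.9 ± 39.8 to 8.12 ± 3.44 CPM and rose in E14 from 0.746 ± 1.05 to 17.3 ± 6.29 CPM (difference −7.14, SE 1.04, adjusted p = 0.014). The epoxide hydrolase gene Ephx2 fell in E14 from 257 ± 4.44 to 3.09 ± 1.57 CPM and did not pass in PGK, at 66.4 ± 47.2 and 59.9 ± 27.8 CPM (difference 6.01, SE 0.89, adjusted p = 0.014). The interferon-induced Ifitm1 (difference 6.4, SE 0.93, adjusted p = 0.014) and T (8.71, SE 1.5, adjusted p = 0.035) differed in the same direction. The T call was lost without either PGK library at day 0 (adjusted p = 0.162 and 0.134), and without the diff3 library of PGK at day 4 its difference was 5.51 (adjusted p = 0.072). For days 27 to 30 against day 0, 8 genes differed, 3 upward and 5 downward in PGK relative to E14, against a median over all genes of −0.2, or −0.95 without the diff2 library of E14 at day 0. Among them Plagl1 measured 217 ± 33.1 and 37.7 ± 2.93 CPM in PGK, and 7.58 ± 1.51 CPM and no counts in E14 (adjusted p = 0.0165 for the difference). It lost its call without any 1 of the 4 PGK libraries or either E14 library of days 27 to 30 (adjusted p = 0.0597 to 0.153). Naive genes as a list fell less in PGK by day 4, with a median difference of 2.24, 0 of 24 singly and 11 when adjusted over the list alone. Camera gave adjusted p = 3.2e-10, and adjusted p = 0.1 with an estimated correlation. Wnt targets differed by 1.9, 1 of 15 singly and 5 when adjusted over the list alone. Their adjusted p was 5.63e-07, and adjusted p = 0.174 with an estimated correlation. Of the 5 called genes named for the first difference 4 lost their call without both shallow libraries, all but Moxd1. That count was 1 without both shallow libraries or without the diff3 library of E14 at day 4, 4 without the diff2 library of PGK at day 4, 5 without the diff3 and 2345 without the diff2 library of E14 at day 0. It was 26 with experiment as a block, 32 with the code term, 52 without a low-count filter, 3265 without the coded libraries and 204 with DESeq2. The second was 1 to 4 when any of the 4 PGK libraries was left out, 4, 4 and 1 without the diff3 library at day 0 and the diff2 and diff3 libraries of days 27 to 30 of E14, and 2286 without its diff2 library at day 0. The same count was 5 without both shallow libraries, 13 without a low-count filter, 3785 without the coded libraries and 110 with DESeq2.

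The other lists fixed beforehand are given here for PGK at day 4 against day 0, as members that rose and fell of those measured, with the counts adjusted over the list alone after them. Core pluripotency had 3 and 1 of 15 (3 and 2), with Utf1 rising from 25.5 ± 14.9 to 228 ± 141 CPM. Neuroectoderm had 6 and 1 of 20 (6 and 2), with Sox11 from 1.08 ± 0.661 to 107 ± 44.1 CPM. Extraembryonic endoderm had 2 and 3 of 18 (3 and 4), and trophoblast 2 and 4 of 16 (2 and 7). DNA methylation machinery had 2 and 3 of 15 (4 and 3), with Dnmt3a rising from 32.5 ± 19.2 to 269 ± 122 CPM and Tet2, which oxidises methylcytosine, falling from 293 ± 186 to 10.9 ± 4.97 CPM. Polycomb and chromatin regulators had 0 and 1 of 20 (0 and 1), and the X inactivation centre 3 and 1 of 10 (3 and 1). Genes that escape X inactivation had 2 and 1 of 16 (2 and 1), microRNA biogenesis 2 and 1 of 21 (2 and 2) and miR-290 and miR-302 targets 2 and 2 of 19 (2 and 4). Glycolysis had 3 and 4 of 18 (4 and 4), with Hk1, a hexokinase gene, falling from 186 ± 73.7 to 23.7 ± 8.14 CPM, and the respiratory chain 0 and 3 of 21 (0 and 3). The p53 list had 1 and 1 of 20 (1 and 3) and the cell cycle list 2 and 1 of 20 (3 and 2). In the latter Ccnd2 rose from 0.554 ± 0.209 to 69.6 ± 61.9 CPM and Ccnd3 fell from 366 ± 6.26 to 70.3 ± 6.68 CPM. The serine and amino acid stress list had 0 and 1 of 15 (0 and 1), the faller being Asns, asparagine synthetase, from 1449 ± 128 to 394 ± 135 CPM. Histones had 0 and 0 of 6, with camera at adjusted p = 0.914, immediate early and heat shock genes 2 and 1 of 15 (2 and 1) and the interferon list 1 and 2 of 14 (6 and 2). None of these lists passed camera in this comparison, the lowest adjusted p being 0.0551 for the respiratory chain, and median and test differed in sign for extraembryonic endoderm, DNA methylation, polycomb, glycolysis and amino acid stress.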

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

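Of the tests for the naive genes in this part, the one for undifferentiated cells and the one without the shallow libraries were chosen after the result or the data were seen. The difference between the changes of the 2 lines was tested with edgeR for genes, and with camera for lists and X-linked genes. With both shallow E14 libraries left out only 1 gene passes for day 4 and 5 for days 27 to 30.

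For day 4 against day 0 the log2 change in PGK minus that in E14 was −2.64 for Acsl4, 3.43 for Atp11a, 6.01 for Ephx2, 5.27 for Gbp2, −10.28 for Heph, 6.4 for Ifitm1, 2.83 for Lgals1, −14.15 for Moxd1, −7.14 for Sema5a, 8.71 for T and −4.73 for Uggt2. For days 27 to 30 against day 0 it was −7.06 for Efhc2, 2.64 for Lgals1, −14.41 for Moxd1, 7.5 for Plagl1, −7.1 for Sema5a, 2.93 for Tenm3 and −5.01 for Uggt2. The values for Moxd1, Heph and Plagl1 rest on groups with at most a few counts and are fitted values, not measured folds. The X-linked minus autosomal median differed by −0.83 at day 4 (adjusted p = 6.29e-12, and adjusted p = 0.0588 with an estimated correlation) and −1.19 at days 27 to 30 (adjusted p = 0.0161 with an estimated correlation). Both values combine a fall in PGK with a rise in E14. Wnt targets differed by a median of 1.9 at day 4 (adjusted p = 5.63e-07, and adjusted p = 0.174 with an estimated correlation).

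The change of naive pluripotency genes to day 4 differed by a median of 2.24 (adjusted p = 3.2e-10, and adjusted p = 0.1 with an estimated correlation), and their level at day 4 was higher in PGK than in E14 by 2.16. Without the shallow E14 libraries these were 2.35 and 2.2, so shallow depth alone does not account for them. The level at day 4 differed by 2.27 within diff2, where both lines are coded, and by 1.75 within diff3, where neither is. The library code alone thus does not account for the level. Each of these checks rests on 1 E14 library at day 4, in diff3 the shallow one, so variation between libraries stays open. A share of undifferentiated cells in the PGK cultures would leave every naive gene at about the same percent only if those cells kept their day 0 levels outside 2i. Whether they did was not measured. Over 16 genes at under 5 percent of day 0 in E14 diff2, the median kept in PGK was at least 7.61 times the lowest. In diff2 1.4 to 26.2 percent was kept (median 10.6), and in diff3 0.104 to 26.8 percent (median 2.38). The lowest gene was Jam2 in both experiments, and the highest in diff3 was Klf5, which kept 4.67 percent in E14 diff2. Unequal percents cannot decide on undifferentiated cells whose own levels had changed. Such a share and a slower exit from the naive state in PGK may both remain, and sex and line cannot be separated in either.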

How the results depend on the processing

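No called gene named here and no list refitted reversed, while the balance of higher and lower calls and the medians over all genes turned in some settings. Of 2150 values of named called genes under an alternative 1958 kept their call and direction and 192 lost the call. RLE size factors changed none of 176. The naming rule favours small adjusted p and large changes, so these shares do not hold for all calls. Of the 231 genes called for PGK day 10 against day 4, 117 were called again in the joint fit and 230 with DESeq2. Of 46 gene list results 7 passed with an estimated correlation. The numbers of genes called were far less stable, and the cause was not tested beyond what each alternative leaves out. Leaving out the coded or the shallow libraries was chosen after seeing the data.

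With experiment as a replicate block, which pairs the libraries, the number called was 351 for PGK day 10 against day 4, 11 for E14 days 19 to 23 against day 10, 44 and 16 for PGK against E14 at days 4 and 10, and 26 for the difference at day 4. Aldh3a1 in E14 lost its call, and the block changed no other call among the 176 named called genes and 46 lists refitted.

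DESeq2 called 3515 genes for PGK day 4 against day 0, 855 for day 10 against day 4, then 5 and 4 for the later steps. For the E14 steps in the same order it called 2856, 520, 274 and 4, and 3597 for days 27 to 30 against day 0. For PGK against E14 it called 700, 235, 78, 89 and 24 by stage, and 204 and 110 for the differences.

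Without the coded libraries the counts were 639 for PGK day 10 against day 4 and 2 for its last step. In E14 they were 6812 for day 4 against day 0, 1111, 1673 and 2 for the later steps and 8039 for days 27 to 30 against day 0. Between lines they were 4633, 538, 504, 446 and 43 by stage, and 3265 and 3785 for the differences. This leaves 1 library per group at days 0, 4 and 10 in both lines, and for E14 at days 0 and 4 it is the shallow one. The spread then comes from the later stages alone. Without both shallow libraries the counts were 887 for E14 day 4 against day 0, 78 and 10 for the next steps, 35 and 15 for PGK against E14 at days 0 and 4, and 1 and 5 for the differences.

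A term for the library code gave 3698 for PGK day 4 against day 0, 655 for day 10 against day 4, 185, 66, 20 and 14 for PGK against E14 at days 0, 4, 10 and 27 to 30, and 32 for the difference at day 4. Without a low-count filter the counts were 439 and 139 for day 10 against day 4 in PGK and E14, 59 for E14 days 19 to 23 against day 10, 181 and 71 for PGK against E14 at days 0 and 4, and 52 and 13 for the differences. In the joint fit they were 133 for PGK day 10 against day 4, and 2423, 208, 18 and 3086 for E14 day 4 against day 0, the next 2 steps and days 27 to 30 against day 0. Limma on the deposited values gave 362 for PGK day 10 against day 4, and RLE size factors 3 for E14 days 19 to 23 against day 10. Among X-linked genes of at least 5 log2 CPM the PGK against E14 median at days 27 to 30 was −0.13 and passed.

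Leaving out each library in turn gave 1366 to 2210 for PGK day 4 against day 0, 52 to 284 for day 10 against day 4 and 2208 to 3644 for days 27 to 30 against day 0. In E14 the same comparisons gave 474 to 4517, 0 to 30 and 645 to 4941, and the later steps of both lines stayed at 0. Between lines the ranges were 24 to 3317, 6 to 35, 9 to 14, 5 to 8 and 5 to 10 by stage, and 1 to 2345 and 1 to 2286 for the differences. X-linked medians ranged from −0.57 to −0.51 and −1.07 to −0.76 in PGK at day 4 and days 27 to 30, 0.53 to 1.23 in E14 at days 27 to 30, and 1.17 to 2.45 and −0.09 to 0 between lines at day 0 and days 27 to 30. Depth sets the floor of 3 counts, at 0.888 and 1.48 CPM in the shallow libraries against 0.111 to 0.253 CPM in the others. Thinned to equal depth, the shallow day 0 library of E14 still had only 10155 genes with counts, against 12837 to 14483 in the others, so depth alone does not account for its fewer genes, and the cause was not tested.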

Other observations

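Of the tests in this part, those for the library code and copy number on chromosome 8, and all those for the X-linked rise in E14 except GC content and length, were chosen after the result was seen.

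Further lists moved between day 0 and days 27 to 30. FGF and ERK targets rose in 11 of 19 cases in PGK at days 27 to 30 against day 0 (equally when adjusted over the list alone, median 1.93, adjusted p = 4.8e-05, and adjusted p = 0.279 with an estimated correlation) and in 10 in E14, with 1 fallen (equally when adjusted over the list alone, median 2.24, adjusted p = 0.000867, and adjusted p = 0.227 with an estimated correlation). Published let-7 targets rose in 11 of 21 cases in PGK and fell in 1 (12 and 1 when adjusted over the list alone, median 0.79, adjusted p = 0.00037, and adjusted p = 0.487 with an estimated correlation). The respiratory chain list lay lower, at −0.56 in PGK with 4 of 21 fallen (8 when adjusted over the list alone, adjusted p = 0.00812, and adjusted p = 0.721 with an estimated correlation) and at −0.46 in E14 with 1 fallen (equally when adjusted over the list alone, adjusted p = 0.00514, and adjusted p = 0.702 with an estimated correlation). Seed matches of microRNA families in 3' untranslated regions gave no adjusted p under 0.05. The differences of medians between genes with and without a match were −0.16 to 0.25 as tested. Matched on length of the region they were −0.13 to 0.1 for families of stem cells and −0.07 to 0.15 for seeds of other tissues.

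Genes on chromosome 8 were higher in PGK than in E14 over all stages, with a median of 0.44 on the log2 scale over 372 genes, while the other 18 autosomes lay between −0.1 and 0.08. All 13 bins of 10 Mb lay above 0, so a few genes or a single region do not account for it. The lowest of 10 pairs of libraries of the same stage and experiment was 0.26, which argues against the library code. After removing a trend on GC content and length the median was 0.45 (bootstrap SE over genes 0.013). A size of 0.44 on a single chromosome, or 1.36-fold, is what an extra copy in many PGK cells or a copy lost in part of the E14 cells could give, and a copy number difference is a candidate explanation that these data cannot settle without DNA.

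X-linked genes lay higher in E14 at days 27 to 30 than at day 0. Without both shallow libraries the X minus autosome value was 0.56. For genes of at least 5 log2 CPM it was 0.26 (SE 0.066) within diff2, which holds neither shallow library. Without the coded libraries it was 1.26, and within diff3, of which no library is coded, 0.33 (SE 0.07) for the same genes. The value was thus above 0 in each experiment. Each experiment sets 1 library against 1, and all SEs here are bootstrap SEs over genes that hold no variation between libraries. Shallow depth and the library code, alone or together, therefore stay open as causes. The largest shift of any autosome was 0.22 against 0.4 (SE 0.12) for the X. After removing a trend on GC content and length 0.28 (SE 0.094) remained. Neither value can tell the explanations apart. No biological explanation was tested.

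In single libraries, chromosome 11 stood 0.36 higher in PGK diff2 at day 29 than in the mean of libraries, against −0.13 to 0.11 in the others, and chromosome 1 stood 0.18 higher in PGK diff3 at days 0 and 4, against −0.11 to 0.05. Chromosome 12 stood 0.23 and 0.19 higher in the same libraries, against −0.18 to 0.16.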
